A study of Arabidopsis thaliana with 12 samples.

How the data were processed

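Expression was measured on 12 one-colour arrays, hybridised with biotin-labelled RNA from the aerial parts of wild-type Arabidopsis thaliana (Columbia) seedlings. Per the labels' protocols, plants grew for 9 days in continuous white light at 22 °C and then spent 24 h in 1 of 4 conditions, so that they were 10 days old at harvest. The conditions combined white light (WL) or white light with supplemental far-red light (WFR) with 22 or 26 °C. Supplemental far-red light imitates the light that neighbouring leaves reflect and is used to start the shade avoidance response. Each condition had 3 arrays, which the labels call biological replicates.

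The deposited table holds 1 log2 value per probe set and array, normalised across arrays by the authors. RMA, affy and MAS5 are named, without versions, per the submitters' processing notes. Which of these gave the deposited log2 values is not given in the sources used here. The array medians lay between 6.91 and 7.01. Arrays give no read depth, so the number of arrays limits the precision.

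Of 22810 probe sets, 64 control probe sets were left out and 22746 were tested. Genes were taken from the platform annotation of the probe sets and updated through RefSeq gene records of the TAIR10.1 assembly, which was used for names only. A single gene was found for 13513 probe sets, of which 13436 were named through RefSeq and 77 kept the platform's name. Another 503 probe sets had several genes and 8730 are unnamed here. The unnamed probe sets entered all counts of calls but no gene list. They include those of many known shade genes: of 11 genes set to be reported whatever their values (ATHB2, PIL1, HFR1, IAA29, XTH15, PIF4, YUC8, FT, CHS, PR1 and HSP101), only IAA29 was named.

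A linear model with 1 mean per condition was fitted to the log2 values of all 12 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without trend). The residual had 8 degrees of freedom and moderation added 5.99. The 7 comparisons were the far-red effect at each temperature, the temperature effect in each light, the difference of the far-red effects (the interaction), and the average far-red and average temperature effects. Tests were two-sided, with Benjamini-Hochberg adjustment over the tested probe sets, and a probe set was called at an adjusted p under 0.05. Errors of log2 differences are the model's standard errors (SE).

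The comparisons, tests, alternatives, gene lists and naming rule below were chosen before the data were examined, except where stated. The 29 gene lists covered hormones, light, temperature, photosynthesis, defence, growth and tissue markers, including root markers. For each gene the probe set with the highest mean over all arrays was used, which gave 13355 genes as background. The 19 lists with at least 3 named members were tested with camera at a preset correlation of 0.01 between genes, and again with an estimated correlation. Adjustment was over the tested lists of a comparison. No member was named for the abscisic acid list or for the indole glucosinolate and camalexin list. Members called measured below are those with a named probe set, and list results cover these alone. They were 3 of the 19 shade markers written, 10 of 46 auxin response genes and 6 of 24 cold response genes. For heat shock they were 3 of 30, for flavonoid synthesis 5 of 33 and for the cell cycle 3 of 40. Because few members were named, 24 gene families that share the letters of a symbol, or the chloroplast genome, and have at least 10 measured genes were added after seeing the data. For each list and family the mean log2 value per array was also tested, after seeing the data, by an exact permutation of the labels within the other factor (400 assignments).

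The genes named in the text follow a rule. For each of the 4 single comparisons and the interaction it takes the 6 largest rises and 6 largest falls among called probe sets with a single gene and with groups that do not overlap. It adds up to 3 called members of each gene list with the largest changes, and the 11 genes above. The rule was applied to the average effects after seeing the data, so genes named for an average effect alone were chosen after their values were seen. Members of a list that did not pass the test and are named as examples were also chosen after their values were seen.

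The fit was tested on simulated data for the far-red effect at 22 °C, with 200 changed probe sets among 22746 in each of 5 rounds. It recovered 88.4% of changes of 0.5 on the log2 scale, 99.7% of changes of 1 and 100% of changes of 2, and 5.13% of its calls were false. In 10 rounds the list test recovered a list of 10 genes moved by 0.3 among 13355 genes each time, and 3.8% of unchanged lists passed at an unadjusted p under 0.05. Simulated genes varied independently of each other, with the same spread in all conditions. The 3.8% therefore does not give the share of false calls for lists whose genes vary together.

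Alternatives were subtraction of array medians or upper quartiles, quantile normalisation, cyclic loess, leaving out the lowest 25% or 50% of probe sets, moderation with trend and robust fitting, the replicate number as a block, array weights, a fit of only the groups compared, stricter thresholds, 1 probe set per gene, and leaving out each array. Leaving out the lowest probe sets tests what signal near the background limits. For the shared calls, the alternatives beyond the replicate block, the stricter adjusted p and the lowest 25% were added after seeing the data, the fits of only the groups compared among them. A change of sign between values that both missed the threshold was not counted as a reversal.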

Results

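The series asked how seedlings respond to supplemental far-red light and to a rise from 22 to 26 °C when the signals are varied independently. Each of the 4 conditions had 3 arrays. Log2 expression values ran from 3.34 to 14.83. Arrays of the same condition correlated across probe sets at 0.99526 to 0.99786, and arrays of different conditions at 0.99328 to 0.99766. These correlations are across genes, which are not independent replicates. The first principal component, with 22.7% of the variance, placed all 6 arrays from 22 °C at negative and all 6 arrays from 26 °C at positive scores.

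At 22 °C, the strongest response to far-red light among named genes was that of IAA29, an auxin-inducible Aux/IAA transcriptional regulator. Its log2 value rose from 5.89 ± 0.171 to 8.04 ± 0.159 (SD, n = 3 each), a 4.44-fold difference (limma, adjusted p = 1.65e-05). HAT2, a homeodomain-leucine zipper factor of the shade response, rose by 0.61 ± 0.12 (SE; adjusted p = 0.0355). The cysteine protease gene AT2G27420 rose 2.29-fold, AT1G80130 2.16-fold and GH9B8, a glycosyl hydrolase family gene, 1.74-fold. The largest falls among named genes were those of the thionin gene AT1G66100, which changed by -0.95 ± 0.187, and of AT1G23390, a Kelch-repeat F-box gene, which changed by -0.84 ± 0.161. Among named genes, AT1G12080 and AT1G65920 also had large rises, at 0.83 and 0.79, and AT1G49500, AT2G41250, AT5G02160 and AT2G15960 large falls, at -0.65 to -0.59. Unnamed probe sets had larger rises, of 2.52 and 2.39, and larger falls, of -1.38 and -1.09.

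Of the 19 shade marker genes written, 3 had a named probe set. IAA29 and HAT2 rose and FHL, chosen after its values were seen, did not pass the limma test (0.18, adjusted p = 0.524). The list ranked above other genes (camera, adjusted p = 8.96e-06), with an adjusted p = 0.0528 with an estimated correlation. IAA29 is also 1 of the 10 measured auxin response genes. Of these, 1 was called over all probe sets and 4 when adjusted over the list alone (camera, adjusted p = 0.00221; adjusted p = 0.111 with an estimated correlation). All 8 measured chlorophyll synthesis genes had negative differences with a mean of -0.15, none was called over all probe sets, and 2 fell when adjusted over the list alone (camera, adjusted p = 0.00395; adjusted p = 0.207 with an estimated correlation). Of 16 expansin and xyloglucan endotransglucosylase genes, EXLA2 rose by 0.40 and 3 rose when adjusted over the list alone (camera, adjusted p = 0.0258; adjusted p = 0.111 with an estimated correlation). Light-harvesting and photosystem genes (7 measured, mean -0.09, 0 called by limma and 0 when adjusted over the list alone) gave a camera adjusted p = 0.0268, and 0.187 as adjusted p with an estimated correlation. Trichome and epidermis markers (3 measured, mean 0.26, 0 called by limma and 1 higher when adjusted over the list alone) gave a camera adjusted p = 0.0285, and 0.207 as adjusted p with an estimated correlation. RR16, a cytokinin-inducible response regulator, rose by 0.60 ± 0.127 (adjusted p = 0.0481). The light-harvesting call was lost with quantile normalisation (adjusted p = 0.11) and cyclic loess (0.138), the trichome call with the same (0.0661 and 0.0615), the expansin call without the lowest 25% or 50% of probe sets (0.0649 and 0.258), the trichome call also without the lowest 25% (0.0649), and the chlorophyll call without WL 22 °C replicate 3 (0.0538) or WFR 22 °C replicate 3 (0.0728). Without WL 22 °C replicate 3 the expansin and trichome calls were also lost (0.161 each), without WFR 22 °C replicate 2 the expansin call (0.0526), without WL 22 °C replicate 1 the light-harvesting call (0.117), and without WFR 22 °C replicate 3 the light-harvesting (0.188) and trichome (0.0728) calls.

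In all, 150 probe sets were called at 22 °C, 108 higher and 42 lower with far-red light, and 67 of them have a single gene. This split changed with the scaling: 57 were higher and 103 lower after subtracting array medians, 64 and 50 after subtracting upper quartiles, 77 and 56 after quantile normalisation, and 88 and 59 after cyclic loess. Median subtraction shifted every far-red difference at 22 °C by -0.0647. GH9B8 lost its call under all 4 scalings (adjusted p of 0.0501 to 0.0583) and HAT2, EXLA2 and RR16 under all but cyclic loess, with HAT2 at 0.0591 after median subtraction. Of the 15 named and called genes, 5 (IAA29, AT2G27420, AT1G65920, AT2G41250 and AT2G15960) stayed called whichever array was left out, and only 10 probe sets were called when the fit held these 2 conditions alone.

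**Figure D1:**
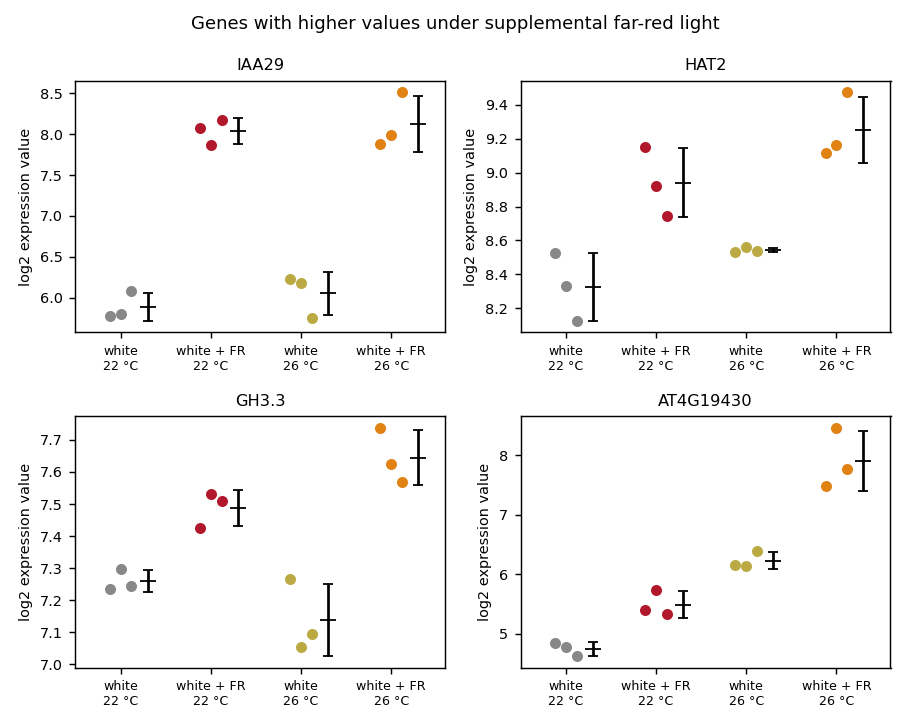
Log2 expression values (y axes, each panel with its own range) of IAA29, HAT2, GH3.3 and AT4G19430 in the 4 conditions (x axes). Points are arrays and black marks the mean ± SD (n = 3); IAA29 had means of 5.89 and 6.05 in white light and of 8.04 and 8.12 with far-red light, at 22 and 26 °C.

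At 26 °C, IAA29 rose by 2.07 ± 0.16 with far-red light, a 4.2-fold difference (limma, adjusted p = 2.71e-05). AT4G19430 rose 3.2-fold and AT5G62280 3.16-fold. GH3.3, an enzyme that conjugates auxin to amino acids, rose by 0.51 ± 0.0731 (adjusted p = 0.0134) and HAT2 by 0.71 ± 0.12 (adjusted p = 0.0475). AT5G12050 and AT5G22460 rose by 0.76 and 0.59, and AT3G44970 was the only called probe set that fell, by 0.70.

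Shade markers again ranked high, with 2 of 3 members called (camera, adjusted p = 4.5e-06), and so did auxin response genes, with 2 of 10 called and 4 when adjusted over the list alone (camera, adjusted p = 1.58e-05). Both calls held with an estimated correlation (adjusted p = 0.0292 for each). The 6 measured cold response genes all had negative differences with a mean of -0.32, and 0 were called by limma over all probe sets or when adjusted over the list alone (camera, adjusted p = 0.000227; adjusted p = 0.0604 with an estimated correlation). Of 5 flavonoid and anthocyanin synthesis genes, 0 were called over all probe sets and 4 fell when adjusted over the list alone, with a mean of -0.39 over the list (camera, adjusted p = 0.000115; adjusted p = 0.254 with an estimated correlation).

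In all, 20 probe sets were called at 26 °C, 19 higher and 1 lower (15 and 2 after subtracting array medians), and 8 have a single gene. The count was 6 to 22 when 1 array was left out and 71 with array weights. HAT2 and AT5G22460 lost their call under each of the 4 scalings, with HAT2 at adjusted p = 0.0862 after median subtraction. Of the 8 named genes, IAA29 and AT4G19430 stayed called whichever array was left out. When the fit held these 2 conditions alone, 22 probe sets were called.

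Averaged over both temperatures, far-red light raised IAA29 4.32-fold, AT5G62280 2.35-fold, AT4G19430 2.32-fold, AT1G80130 2.02-fold and AT2G47880 1.74-fold (limma, adjusted p = 0.0042 for the last). The auxin-conjugating enzyme genes WES1 (GH3.5) and GH3.3 rose by 0.57 ± 0.0809 and 0.37 ± 0.0517, and WSD1, a wax ester synthase gene, by 0.51 ± 0.0824. ATSPS4F, a sucrose-phosphate synthase gene, rose by 0.30 ± 0.0566. AT1G66100, AT3G44970, AT1G23390, AT1G49500, AT2G41250 and AT4G30650 fell by 0.75, 0.60, 0.59, 0.45, 0.45 and 0.45. EXLA2 rose by 0.23 and RR16 by 0.41, but both lost their call under each of the 4 scalings (adjusted p of 0.0951 to 0.125 and 0.0526 to 0.0676). ATSPS4F lost its call after median subtraction (0.0504).

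For the average far-red effect, 2 of 3 shade markers and 3 of 10 auxin response genes were called (camera, adjusted p = 2.19e-06 and 6.38e-05), and both lists held with an estimated correlation (adjusted p = 0.0391 and 0.0415). The auxin list had 5 higher when adjusted over the list alone. Cold response genes (6 of 6 negative, mean -0.24, 0 called by limma and 2 lower when adjusted over the list alone) gave an adjusted p = 0.00156, and an adjusted p = 0.0995 with an estimated correlation. Chlorophyll synthesis genes (8 of 8 negative, mean -0.10, 0 called by limma and 0 when adjusted over the list alone) gave an adjusted p = 0.00318, and an adjusted p = 0.229 with an estimated correlation. Light-harvesting genes (mean -0.07, 0 of 7 called by limma and 0 when adjusted over the list alone) gave an adjusted p = 0.00717, and an adjusted p = 0.104 with an estimated correlation. Their call was lost with quantile normalisation (adjusted p = 0.0948) and cyclic loess (adjusted p = 0.125). Trichome and epidermis markers (mean 0.22, with WSD1 as the 1 of 3 called, also when adjusted over the list alone) gave an adjusted p = 0.0334, and an adjusted p = 0.229 with an estimated correlation. This call was lost with quantile normalisation (adjusted p = 0.0839), cyclic loess (0.0923) and without WL 22 °C replicate 3 (0.108), WFR 22 °C replicate 2 (0.0524), WL 26 °C replicate 1 (0.0942) or WFR 26 °C replicate 2 (0.113).

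At an adjusted p under 0.05, the average far-red effect had 255 called probe sets, 188 higher and 67 lower. Their number was 98 to 253 when 1 array was left out and 835 with array weights. The split was 106 and 150 after subtracting array medians, 123 and 92 after upper quartiles, 129 and 82 after quantile normalisation, and 130 and 80 after cyclic loess. Of the calls at 22 °C and at 26 °C, 17 were common and in the same direction. These calls share 1 estimate of the spread, so independent lists are no reference for them. In fits of only the conditions compared, which share neither arrays nor that estimate, 10 probe sets were called at 22 °C and 22 at 26 °C, and 7 were common and in the same direction, where independent lists would share 0.00835. The 255 had a median size of 0.412 at 22 °C and 0.291 at 26 °C.

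**Figure D2:**
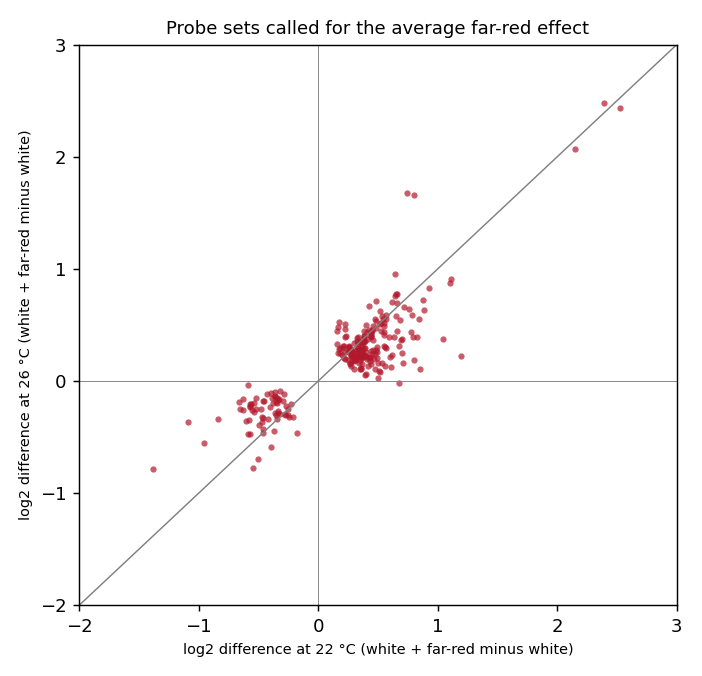
Far-red effects (log2 difference, white plus far-red minus white) at 22 °C (x axis) and 26 °C (y axis) of the 255 probe sets called for the average far-red effect. Each point is a probe set and the diagonal marks equal effects; the median size is 0.412 at 22 °C and 0.291 at 26 °C.

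In white light, the rise to 26 °C raised CSLA01, a gene of the glucomannan synthase family, with a difference of 1.58 ± 0.263 (limma, adjusted p = 0.0126). AT4G17470 rose 2.84-fold, AT4G19430 2.8-fold and AT5G48570, which encodes the heat-inducible peptidyl-prolyl isomerase ROF2, 2.77-fold (adjusted p = 0.000772). AT5G12110, a translation elongation factor gene, rose by 1.34 ± 0.0843 (adjusted p = 1.88e-06). AT5G55450, AT4G30650, 2A6 and AT5G49560 fell by 0.94, 0.64, 0.57 and 0.57, and AT1G30820 and AT1G55265 by 0.53 and 0.50. AT1G55265 lost its call after subtracting upper quartiles (adjusted p = 0.0544) and with cyclic loess (0.0551). A second probe set of 2A6 had the opposite sign, with 0.38 against -0.57.

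IAA29 differed by 0.17 ± 0.16 between the temperatures in white light, less than its error allows to call (adjusted p = 0.733). No gene list passed camera in white light. The nearest were cold response, heat shock, expansin, flavonoid and trichome lists, all at adjusted p = 0.0511. In all, 139 probe sets were called, 103 higher and 36 lower at 26 °C, against 76 and 47 after subtracting array medians. Leaving out 1 array gave 44 to 152 calls, and array weights gave 1614. Of the 12 named and called genes, 6 (AT4G17470, AT4G19430, AT5G48570, AT5G12110, AT5G55450 and 2A6) stayed called whichever array was left out.

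With far-red light, AT4G19430 rose 5.34-fold from 22 to 26 °C (limma, adjusted p = 1.95e-05) and AT1G62510 4.85-fold (adjusted p = 0.000779). AT5G48570 rose 2.32-fold, the beta-glucosidase gene BGLU28 2.23-fold, AT5G12110 2.16-fold and Hop3, a co-chaperone of HSP70 and HSP90, 1.85-fold. YUC2, an enzyme of auxin synthesis, rose by 0.39 ± 0.0766 (adjusted p = 0.0286). The largest fall among named genes was that of the lectin gene AT5G03350, which changed by -1.43 ± 0.314 (adjusted p = 0.0454), followed among named genes by AT5G55450 at -0.998 and AT2G23910 at -0.93. Unnamed probe sets fell by up to 1.91. RR16 fell by 0.72 and ATSPS4F by 0.39, and AT1G78450, AT3G15650 and AT1G35710 by 0.86, 0.82 and 0.80.

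In far-red supplemented light, the 6 cold response genes all had negative differences with a mean of -0.53. None was called over all probe sets and 4 fell when adjusted over the list alone (camera, adjusted p = 0.00143; adjusted p = 0.207 with an estimated correlation). Of 3 measured heat shock genes only AT5G48570 was called (camera, adjusted p = 0.0102; adjusted p = 0.24 with an estimated correlation). ATHSP22.0 and HSA32, both at 0.13 and chosen after their values were seen, did not pass. The list call was lost without WFR 22 °C replicate 3 (adjusted p = 0.0982) or WFR 26 °C replicate 3 (0.0529). There were 250 called probe sets, 127 higher and 123 lower at 26 °C, and this number was 40 without WFR 26 °C replicate 2 and 379 without WL 22 °C replicate 3. Of the 15 named and called genes, 6 (AT4G19430, AT1G62510, AT5G48570, AT5G12110, Hop3 and AT5G55450) stayed called whichever array was left out, and AT5G03350, BGLU28, YUC2 and RR16 did not.

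Averaged over both lights, temperature gave the most calls. AT4G19430 rose 3.86-fold, AT1G62510 3.46-fold, the jacalin-related lectin gene JAL23 2.83-fold, CSLA01 2.55-fold, AT5G48570 2.54-fold and AT1G54020 2.51-fold (limma, adjusted p = 0.0178 for the last). COR15A and COR15B, cold-induced chloroplast proteins, fell by 0.70 ± 0.125 (adjusted p = 0.00671) and 0.51 ± 0.108 (adjusted p = 0.0148), and COR27 fell by 0.56, with a call that was lost when 1 of several arrays was left out (adjusted p of up to 0.0749). The chitinase family gene AT2G43590 fell by 1.13 ± 0.21, AT5G03350 by 1.11, AT5G55450 by 0.97, AT1G17665 by 0.66 and AT4G30650, of a family of low-temperature responsive membrane proteins, by 0.62. WES1 rose by 0.38 ± 0.0809, YUC2 by 0.26 ± 0.0542 and WSD1 by 0.35, and RR16 fell by 0.52 and ATSPS4F by 0.31.

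Of 6 cold response genes, 3 fell and 4 did when adjusted over the list alone (mean -0.44; camera, adjusted p = 0.00178; adjusted p = 0.221 with an estimated correlation). LTI30 and STZ, chosen after their values were seen, differed by -0.91 (adjusted p = 0.059) and 0.13 (adjusted p = 0.623). Of 3 heat shock genes, 1 rose, also when adjusted over the list alone (mean 0.49; camera, adjusted p = 0.0192; adjusted p = 0.318 with an estimated correlation). The call was lost without WFR 22 °C replicate 3 (adjusted p = 0.075), WL 26 °C replicate 3 (adjusted p = 0.0683) or WFR 26 °C replicate 3 (adjusted p = 0.0571). Both measured members of the aliphatic glucosinolate list, of 24 written, rose, BCAT4 by 0.39 ± 0.0725 and UGT74B1 by 0.38 ± 0.0665 (limma, adjusted p = 0.00765 and 0.00643). This list of 2 was too small for camera.

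**Figure D3:**
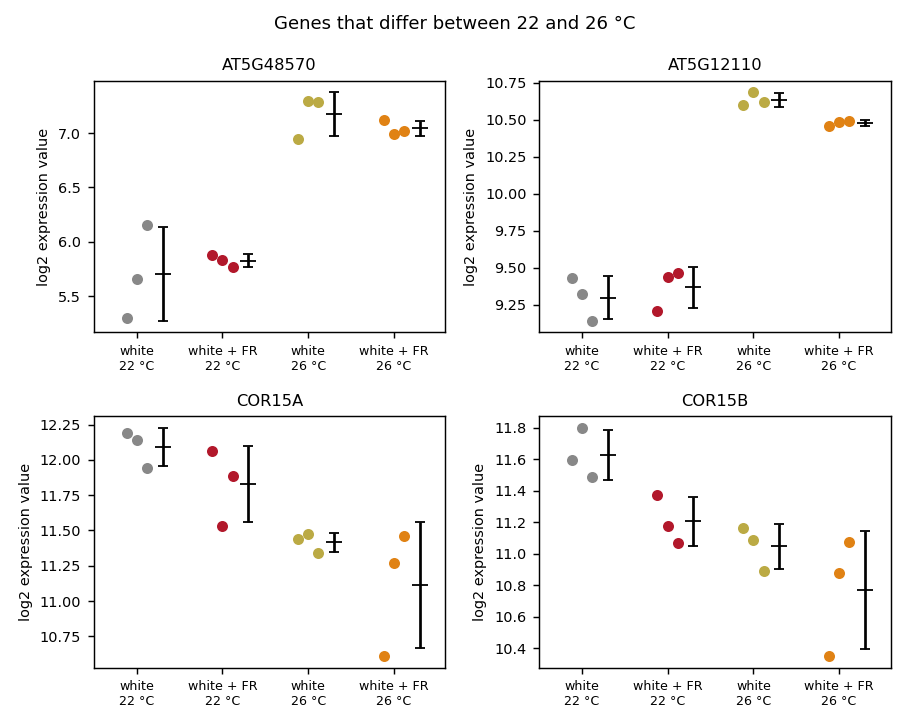
Log2 expression values (y axes, each panel with its own range) of AT5G48570, AT5G12110, COR15A and COR15B in the 4 conditions (x axes). Points are arrays and black marks the mean ± SD (n = 3); in white light the means at 22 and 26 °C were 5.70 and 7.17 for AT5G48570 and 12.09 and 11.42 for COR15A.

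The average temperature effect had 1227 called probe sets, 664 higher and 563 lower at 26 °C. Their number was 655 to 1357 when 1 array was left out and 2247 with array weights. Of the calls in white and in far-red supplemented light, which share the estimate of the spread, 59 were common and in the same direction (40 higher and 19 lower) and 0 were opposite. In fits of only the conditions compared, 22 were common and in the same direction among 57 and 147 calls, where independent lists would share 0.182, and 0 were opposite. The 1227 had median sizes of 0.271 in white and 0.295 in far-red supplemented light. Of the named and called genes, 19 of 21 for the average temperature effect and 14 of 19 for the average far-red effect stayed called whichever array was left out. COR27 and WSD1 were the 2 that did not for temperature.

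The difference of the far-red effects between 26 and 22 °C called 0 probe sets with limma, and the smallest adjusted p was 0.0891. At an unadjusted p under 0.05 there were 1254 probe sets, 5.51% of those tested. IAA29 had a difference of -0.08 ± 0.226. With array weights, 2 probe sets were called. As gene lists, flavonoid and anthocyanin synthesis (DFR, UGT78D1, UGT78D2, UF3GT and AT5MAT, named after their values were seen) had a mean difference of -0.48, all 5 genes negative, and 3 lower when adjusted over the list alone (camera, adjusted p = 0.000239; adjusted p = 0.309 with an estimated correlation). Expansin and xyloglucan endotransglucosylase genes (mean -0.11) and 3 cell cycle genes (mean 0.21) passed camera at adjusted p = 0.0403 each. Adjusted over the list alone, 1 of 16 expansin and xyloglucan genes was higher and 2 lower, and 0 cell cycle genes were called by limma. Both had an adjusted p = 0.309 with an estimated correlation. Both were lost when 1 array was left out, at most at 0.494 for expansins (without WL 22 °C replicate 3) and 0.231 for cell cycle genes (without WFR 22 °C replicate 3), and the expansin call was lost with quantile normalisation (0.0701) and cyclic loess (0.0923).

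**Figure D4:**
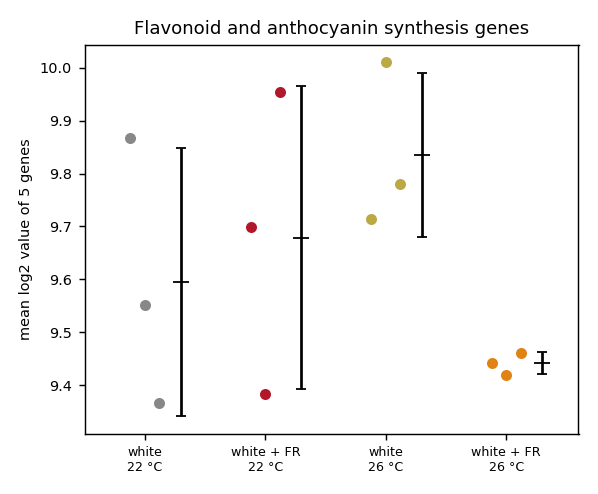
Mean log2 value per array (y axis) of the 5 measured flavonoid and anthocyanin synthesis genes in the 4 conditions (x axis). Points are arrays and black marks the mean ± SD (n = 3); the arrays of white plus far-red light at 26 °C lie at 9.42 to 9.46, those of white light at 26 °C at 9.72 to 10.01.

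Between the average far-red and the average temperature effects, 23 calls had the same direction and 28 the opposite. Independent lists would share 5.49 higher in both, 1.66 lower in both and 6.61 opposite, against 19, 4 and 28 observed, but both effects share the arrays' estimate of the spread, which these values leave out. AT4G19430, WES1 and WSD1 rose with both signals, and AT3G44970 and AT4G30650 fell with both. RR16 and ATSPS4F were called higher with far-red light and lower with temperature, but their far-red calls were lost after median subtraction and when 1 of several arrays was left out. Over all probe sets the average effects correlated at -0.06, across genes that are not independent replicates.

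The other tested lists did not pass camera in the average effects, with mean differences of -0.25 to 0.13 for far-red light and -0.10 to 0.195 for temperature. For far-red light the adjusted p was 0.889 for auxin synthesis and transport, 0.53 for gibberellin, 0.765 for salicylic acid defence, 0.53 for jasmonate response, 0.339 for flowering time, 0.128 for starch and sucrose metabolism, 0.139 for expansins, 0.176 for heat shock, 0.139 for flavonoid synthesis, 0.61 for cell cycle, 0.22 for guard cell and stomatal lineage markers and 0.959 for meristem and organ boundary markers. For temperature the adjusted p was 0.287 for auxin synthesis and transport, 0.377 for gibberellin, 0.97 for salicylic acid defence, 0.62 for jasmonate response, 0.97 for flowering time, 0.21 for starch and sucrose metabolism, 0.21 for shade markers, 0.821 for auxin response, 0.378 for expansins, 0.0649 for light-harvesting, 0.287 for chlorophyll synthesis, 0.97 for flavonoid synthesis, 0.62 for cell cycle, 0.081 for trichome markers, 0.651 for guard cell markers and 0.287 for meristem markers. Root markers, a tissue that the aerial samples should lack, gave 0.856 for far-red light and 0.558 for temperature. These tests of a change between conditions cannot show whether root tissue was absent. The mean log2 value of the 4 named root markers (PYK10, EXPA7, EXPA18 and SPR1, named after their values were seen) was 8.30 to 8.44 over the conditions, while array medians were 6.91 to 7.01. A mean over 4 genes does not show which of them were high, so it neither shows nor excludes root tissue. Mean and median differed in sign for auxin synthesis and root markers with far-red light, and for auxin response, flavonoid synthesis, jasmonate response, flowering time and root markers with temperature. The lists too small for camera, whose genes were named after their values were seen, held EIN3 and RTE1 (ethylene), BRL1 and BIM1 (brassinosteroid), GI (clock), HYH (light signalling), CLE41 and CLE44 (vascular), SPL and AMS (floral organs) and ARR15 beside RR16 (cytokinin), and of these genes only RR16 was called in the average effects.

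As a check of RNA quality, the 3' minus 5' log2 difference of control transcripts was 0.533 to 0.898 for GAPDH, 2.86 to 3.53 for actin and 1.24 to 1.4 for ubiquitin over the 12 arrays. In exact permutation tests within the other factor, two-sided with 400 assignments, the differences with far-red light were -0.0279 (p = 0.675), 0.119 (p = 0.29) and -0.0127 (p = 0.65). The same exact permutation test gave differences with temperature of 0.0647 (p = 0.275), 0.0529 (p = 0.64) and -0.0238 (p = 0.415).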

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

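The tests of normalisation, of RNA quality, of single arrays, of replicate spread and of the share of larger effects, the tests of the flavonoid list, and the adjustment of the interaction over called probe sets, were chosen or given their bounds after the results were seen.

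The far-red response of flavonoid and anthocyanin synthesis genes differed between 26 and 22 °C by a mean of -0.48 on the log2 scale in the interaction test. Leaving out 1 array brought this no nearer to 0 than -0.34, which argues against a single array as the whole source. The 5 genes vary together between replicates, with an estimated correlation between genes of 0.684, and a permutation of residuals of their mean per array gave p = 0.0562. Joint variation of the pathway between replicates therefore stays open, and so does a dependence on temperature of the far-red response, which may exist but is not established by these 12 arrays.

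Far-red calls were mostly higher, with 73.7% of the 255 averaged calls. After subtracting array medians 41.4% were higher, and 57.2% to 61.9% under the other 3 scalings. Median subtraction shifted every averaged far-red difference by -0.0464, and their median went from 0.0087 to -0.0377. This median was 0.00129 with quantile normalisation and -0.000725 with cyclic loess, where 61.1% and 61.9% of calls were higher. Part of the balance of directions may thus come from the normalisation between arrays, but it reversed only with the shift by medians. The fewer calls at 26 °C stayed mostly higher (15 of 17 after median subtraction). The smallest p of the 3 control transcripts for RNA quality, averaged over the temperatures, was 0.29 (permutation test), which leaves a difference open. At 22 °C alone the 3' minus 5' value of actin was 3.04 ± 0.167 in white light and 3.36 ± 0.169 with far-red light (SD). An exact permutation of these arrays, with few possible assignments, gave p = 0.2. At 26 °C the values were 3.29 and 3.21 (exact permutation p = 0.7). A far-red response that raises more genes than it lowers is the open biological alternative, untested apart from scaling.

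Far-red light gave 150 calls at 22 °C and 20 at 26 °C in the fit of all 12 arrays, but 10 and 22 when only the groups compared were fitted, so the contrast in counts rests on the joint fit. The sampling variance of the far-red effect at 26 °C was 0.749 of that at 22 °C, so the spread was not larger at 26 °C. The joint fit gave both far-red effects 1 shared estimate of the spread, so this ratio cannot decide what set the counts. It leaves open that the shared estimate was too small at 22 °C and too large at 26 °C. A single array is argued against by the 45 calls made at 22 °C at the lowest when 1 array was left out, against 22 at most at 26 °C. With equal effects at both temperatures, 67 of 99 permutations of whole-array residuals gave a difference in calls as large as the real 130. The largest permuted difference, calls at 22 °C minus calls at 26 °C, was -2248. Moving residuals between arrays adds random differences between the conditions to the fitted effects, so a difference of 130 is easily reached. The 67 of 99 therefore cannot decide, and array-to-array variation stays open for the counts. By another measure, the 74.1% of averaged calls with the larger effect at 22 °C, only 2 of 99 permutations were as far from 50%, but these permutations even out the larger spread at 22 °C, which keeps this open. A weaker far-red response at 26 °C is therefore a hypothesis that these measures do not decide.

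Other effects passed a test of their difference between conditions. The far-red effect of expansin and xyloglucan endotransglucosylase genes differed between 26 and 22 °C by a mean of -0.11 and that of cell cycle genes by 0.21 (camera, adjusted p = 0.0403 each, and adjusted p = 0.309 each with an estimated correlation). Among calls of the average far-red effect, with adjustment over those calls, the interaction was 0.55 for AT2G15960 (limma, adjusted p = 0.0384; far-red effects of -0.59 at 22 °C and -0.03 at 26 °C). It was -0.69 for an unnamed probe set (adjusted p = 0.000999). Among calls of the average temperature effect the interaction was -0.86 for AT3G28270, chosen after its values were seen (adjusted p = 0.0483; temperature effects of 1.05 in white and 0.18 in far-red supplemented light), and -0.9995 for an unnamed probe set (adjusted p = 0.0483). None of these probe sets passed with adjustment over all probe sets.

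Other splits of the samples were counted for each comparison. The average far-red effect had 255 calls, against 4 at most in the other splits drawn within temperature, and 1 of 100 splits, the real one, gave as many. The average temperature effect had 1227 calls, against 12 at most, and 1 of 100 splits gave as many. For both averages, random regrouping of the arrays thus rarely gave as many calls, and 1 of 100 is the lowest share possible here. The splits cannot address a cause that goes with the conditions. For the single comparisons the 10 possible splits are too few for a share under 0.05: the real values were 150, 20, 139 and 250 calls, the highest others 1, 1, 0 and 0, and 1 split each gave as many. For the interaction, 37 of 100 regroupings of residuals gave at least the 1254 probe sets at an unadjusted p under 0.05, with a highest of 2561, so chance is not excluded.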

How the results depend on the processing

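Scaling by array medians, upper quartiles, quantiles or loess, and leaving out the lowest 25% of probe sets, kept all counts within 1.5 times, although the direction of far-red calls moved as reported. The probe sets called changed more. After median subtraction, 99 of the 150 far-red calls at 22 °C and 173 of the 255 averaged far-red calls were still called, against 1169 of 1227 for the average temperature effect. Counts are given in the order far-red at 22 and 26 °C, temperature in white and in far-red supplemented light, average far-red and average temperature. With array weights they were 398, 71, 1614, 307, 835 and 2247, and 2 for the interaction. At least 2-fold they were 9, 5, 21, 14, 7 and 20, at an adjusted p under 0.01 25, 6, 39, 41, 67 and 330, and with 1 probe set per gene 55, 8, 68, 123, 120 and 585. The last setting also left out the 8730 unnamed probe sets and the 503 with several genes. Of the main calls only 67, 8, 70, 128, 127 and 624 have a single gene. With only the groups compared the counts were 10, 22, 57 and 147 for the single comparisons, which turned the order of the far-red counts, and shared calls were 7 for far-red and 22 for temperature. For temperature in white and in far-red supplemented light, leaving out the lowest 50% gave 220 and 422, and trend with robust moderation 218 and 448. With the replicate number as a block, counts were 84, 16, 88, 138, 172 and 933, and 0 for the interaction. As a check of pairing, deviations of arrays with the same replicate number correlated at -0.259 to 0.12, and 2 of 12 arrays correlated best with their own number. Shared calls of far-red at both temperatures, of temperature in both lights, and of the averages in the same and in opposite directions were 43, 166, 76 and 129 with array weights and 5, 13, 4 and 2 at an adjusted p under 0.01. With the replicate block, far-red at both temperatures shared 11, temperature in both lights 37 and the averages in opposite directions 18. Temperature in both lights shared 100 without the lowest 50% and 99 with trend and robust moderation, which gave 48 for the averages in opposite directions. Leaving out 1 array gave 45 to 135, 6 to 22, 44 to 152, 40 to 379, 98 to 253 and 655 to 1357 calls, 0 to 0 for the interaction, and 4 to 14, 17 to 57, 9 to 31 and 7 to 34 shared calls. The lowest numbers came without WFR 22 °C replicate 1, WL 26 °C replicate 2, WL 26 °C replicate 3, WFR 26 °C replicate 2, WFR 26 °C replicate 3 and WL 26 °C replicate 2. No called log2 difference or list changed direction, but the majority of far-red calls at 22 °C (57 higher and 103 lower) and averaged did after median subtraction. Of 94 values of named genes, 9 lost their call after median subtraction, 9 after upper quartiles, 8 with quantile normalisation, 6 with cyclic loess, 14 with trend and robust moderation, 14 with the block and 0 with array weights. With an estimated correlation 19 list calls were lost, and so were all 4 family calls. The list calls that held were those of shade markers and auxin response genes, for far-red light at 26 °C and averaged. Both of these lists include IAA29. Stricter thresholds lower counts by construction, and 1 probe set per gene did so largely by leaving out probe sets without a single gene. The cause was not tested for the other changes.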

Other observations

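All tests in this part were chosen after the data were seen, and the families tested are 24.

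The 11 measured genes with autophagy symbols, mostly of the ATG8 family, had a mean difference of 0.18 on the log2 scale for the average temperature effect, with 10 of 11 positive and 3 called over all probe sets. The largest, chosen after their values were seen, were ATG8B at 0.39, ATG8E at 0.32 and ATG8D at 0.31. Camera gave an adjusted p = 8.1e-06 over the families, and an adjusted p = 0.155 with an estimated correlation. The family also passed in each light, a call lost with an estimated correlation in both (adjusted p = 0.514 in white and 0.233 in far-red supplemented light) and in white light without the lowest 50% of probe sets (0.105). A rise of this family with temperature may be a candidate for follow-up: the exact permutation p of its mean per array was 0.005, the smallest that 400 assignments allow, but 0.12 after adjustment over the families.

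The 69 chloroplast-encoded genes had a mean difference of 0.097 and a median of 0.02 with far-red light, with 46 positive and 4 called higher. The exact permutation p of their mean per array was 0.035, and 0.18 after adjustment over the families, so a joint rise with far-red light may exist but did not pass. For the average effect camera gave an adjusted p = 0.08, and an adjusted p = 0.699 with an estimated correlation. At 26 °C alone the set passed camera (adjusted p = 0.0229), but not with an estimated correlation (adjusted p = 0.962), with array weights (0.497), without the lowest 25% or 50% of probe sets (0.0624 and 0.218) or without any 1 of 4 of the 6 arrays compared (up to 0.397).

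The mean of each fixed list per array was tested by exact permutation, two-sided. With adjustment over the 19 lists, shade markers (0.95), auxin response genes (0.35) and cold response genes (-0.24) passed for the average far-red effect, each at an exact permutation p = 0.005, the smallest that 400 assignments allow (adjusted 0.0317). IAA29, at 2.11, is in the first 2 lists and carries much of both means: FHL differed by 0.08, and the median of the auxin list was 0.12, with 7 of 10 positive. For temperature, heat shock genes (0.49), cold response genes (-0.44) and meristem and boundary markers (-0.09) passed at the same exact permutation p and adjusted value. The heat shock mean rests on AT5G48570, at 1.34, since the other members had 0.07 and 0.05. Light-harvesting genes passed for both, with -0.07 for far-red light and 0.08 for temperature (exact permutation p = 0.01, adjusted 0.0475). Unlike camera, this test does not compare a list with other genes. It used the deposited values alone, so its dependence on scaling was not tested, which matters most for small means such as those of light-harvesting genes.

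Among unnamed probe sets, the largest average rises with far-red light were 2.48 and 2.44 and the largest falls -1.08 and -0.73. With temperature the largest average rises were 2.53 and 1.96 and the largest falls -1.45 and -1.16.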
